A study of Ascaridia galli and Trichostrongylus colubriformis with 4 samples.

How the data were processed

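Poly(A) RNA of whole worms was sequenced from 2 nematodes, *Ascaridia galli* taken from chickens and *Trichostrongylus colubriformis* taken from sheep, each exposed in vitro to an aqueous extract of the moss *Pottia lanceolata* or to distilled water. Per the labels' protocols, worms came from the intestines of slaughtered hosts, assay concentrations of the extract were 10, 20 and 50 mg/ml, and libraries were made with the NEBNext Ultra kit from 110 to 350 ng of total RNA with 12 PCR cycles and read on an Illumina HiSeq. The concentration used for the RNA, the aligner's settings and the assembly's build are not given in the sources used here. The cestode worms and the reference drug named in the labels are not analysed here.

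The data are 1 table per worm with a line per unigene. Per the file headers, the authors' deposited values are normalized counts of conditions A and B, their mean, the fold change (a ratio), its log2, a p-value and an adjusted p-value, an up, down or neutral mark, and the best protein hit with its percent identity. The submitters' processing notes credit the differential analysis to DESeq, whose version is not given there. Per the file headers the conditions are called A and B and nothing says which is extract and which is water. The groups planned as treated and control could therefore not be assigned, and all results are given as condition B over condition A.

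Only unigenes with reads in both conditions are listed, so a transcript seen in 1 condition alone is not part of these data. The *A. galli* table held 150798 unigenes, of which 55354 (36.7%) had a protein hit, and that of *T. colubriformis* held 43810, of which 22595 (51.6%) had a hit. A stray header line in the *A. galli* table, with 1 read in each condition, was left out. All hits were entries of nematodes, so host and bacterial proteins could not appear as hits. Whole reads were recovered from the step size of the deposited normalized counts (all values up to 200, the range checked, were whole within 0.1 read): 87659967 and 69118994 reads for conditions A and B of *A. galli*, and 91182265 and 91812201 for *T. colubriformis*. Most counts were even (71.4% to 82.8%), as when both mates of a pair are counted, so the 95% counting intervals used the reads divided by 2, in an exact (Clopper-Pearson) binomial interval of the ratio.

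Log2 ratios were computed from the authors' deposited normalized counts with a pseudocount of 1. A unigene was tested against the size rule of at least 4-fold when the higher condition had at least 20 normalized counts. There is 1 library per group, so there are no replicates, no test between groups was made, and shares and percentiles are a description of these libraries. The lists of genes, 37 in all, were matched by product name and fixed before the data were examined, as were the size rule, the minimum counts and most of the alternative settings. For a list with at least 5 members with a mean of at least 10 normalized counts, the median log2 ratio was set against 10000 random lists of annotated unigenes drawn from the same 20 bins of abundance, and called outside when it lay beyond the central 95%.

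Named transcripts followed a rule fixed in advance. Per worm they were the 10 largest rises and 10 largest falls among annotated unigenes with at least 100 normalized counts, ranked by the bound of the counting interval nearest 0, with 1 unigene per product name and without uninformative names. To these were added the 2 most abundant members of each list outside its range, the most abundant member of each drug-target list and the 5 most abundant annotated unigenes. The last were planned for the control library and are taken from both conditions, since the control is unknown; a few are given as examples.

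The size rule was tested on simulated data. Well-covered unigenes were changed 8-fold or 16-fold in counts drawn at the observed depth with counting error alone. They were called under total scaling, and 200 of 200 were found in both worms. Unchanged unigenes were called in 0.272% to 0.284% of cases in *A. galli* and 0.115% to 0.126% in *T. colubriformis*. These rates leave out variation between worms and changes in unigenes with few reads, so they are not error rates of the real comparison. Of 100 random lists of 30 members, 5 were called in each worm; a list shifted by 1.5 on the log2 scale was found in 99 of 100 draws in *A. galli* and in 42 of 100 in *T. colubriformis*, where list medians vary more.

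Alternatives were another scaling (total counts, or the trimmed mean of M-values with 30% of log ratios and 5% of levels trimmed), a pseudocount of 5, no minimum or a minimum of 100, a 2-fold threshold, the counting interval in place of the ratio, annotated unigenes only, a list minimum of 50 and 1 unigene per product name. Alternatives added after the data were seen were counts summed per best-hit protein, ascaridid hits only, a minimum of 1000, the trimmed mean of M-values for the lists, and the other scalings for product families, added lists and lists split by best hit. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.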

Results

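Whole worms of 2 parasitic nematodes were compared after contact with an aqueous extract of the moss *Pottia lanceolata* or with distilled water: *Ascaridia galli*, the large roundworm of the chicken intestine, and *Trichostrongylus colubriformis*, a small hair-like worm of the sheep intestine. The question is which transcripts differ between worms kept in extract and worms kept in water. Each worm had 1 library per condition, 4 in all, and there were no replicates. The authors' deposited table for each worm names its conditions A and B without saying which is the extract, so every ratio is given as condition B over condition A and no direction of a response to the extract is stated. The order of A and B can differ between the worms. With 1 library per group, no test between conditions was possible. Counting intervals (95%) cover counting error alone and not the variation between worms.

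In *A. galli*, transcripts of major sperm protein were lower in condition B, as was the list of unigenes matched by name to tubulin. A large set of low-abundance transcripts with bacterial-type product names was higher. Major sperm protein, the cytoskeletal protein that moves the crawling sperm of nematodes, showed the lowest median of all the gene lists tested in this worm. Abundant transcripts were somewhat lower as a whole, and few changed by large factors. Of 10229 unigenes (the table's transcripts) with at least 1000 normalized counts in the higher condition, 86.8% lay within 4-fold and 0.704% differed by more than 32-fold; their median log2 ratio was -0.73 (-0.30 under total scaling).

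Of 114411 *A. galli* unigenes with at least 20 normalized counts in the higher condition, 25961 (22.7%) were at least 4-fold higher in condition B and 11163 (9.76%) at least 4-fold lower, so that 69.9% of these differences were toward condition B. At the deposited scaling the excess was one of unigenes with few counts. With a minimum of 100 the counts were 4263 higher and 4973 lower, and with a minimum of 1000 they were 487 and 866. Scaling on total counts shifted the log2 ratios by 0.38 before the pseudocount and gave 34163 higher and 6767 lower, 83.5% toward condition B; scaling by the trimmed mean of M-values shifted them by 0.14 and gave 28910 and 9291. The middle 50% of the unigenes' log2 ratios ran from -1.0 to 1.64. In *T. colubriformis* the same range ran from -3.75 to 3.07.

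**Figure D1:**
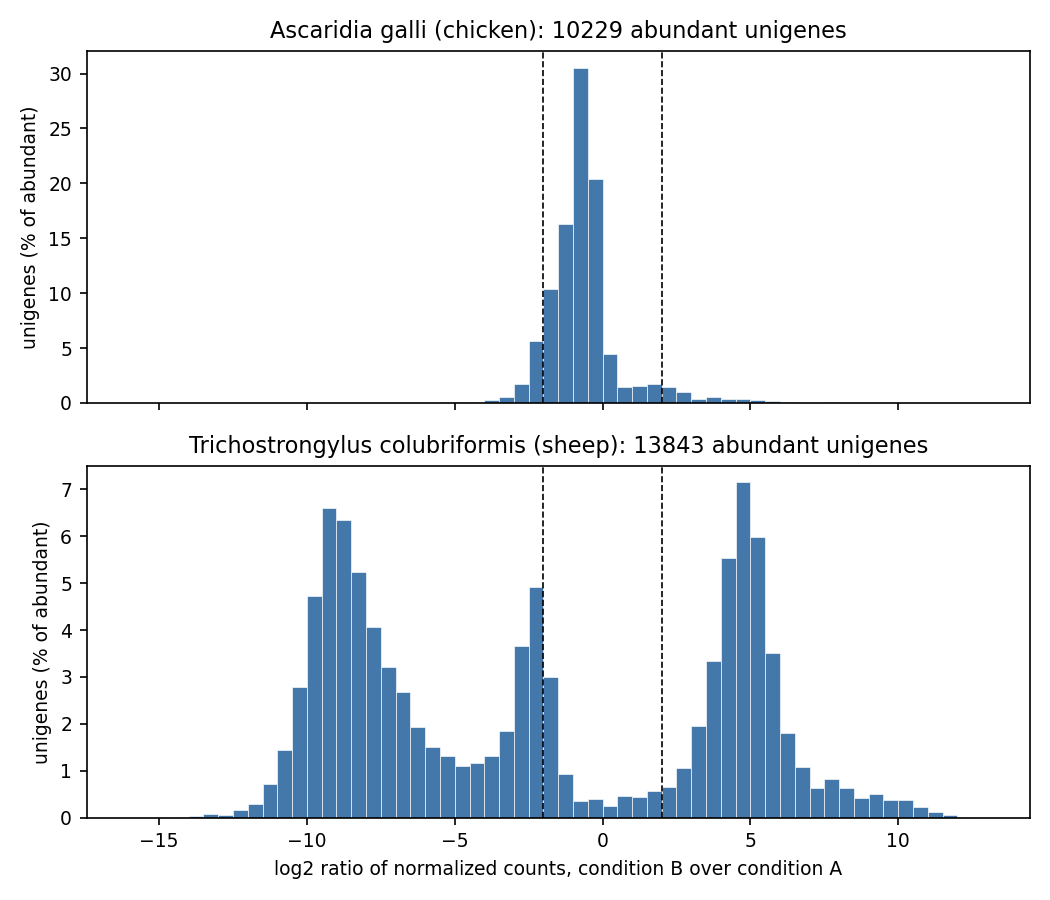
Distribution of the log2 ratio of normalized counts (condition B over condition A, x axis) as the percent per bin (y axis) of the unigenes with at least 1000 normalized counts in the higher condition, 10229 in *A. galli* and 13843 in *T. colubriformis*; dashed lines mark 4-fold. The chicken worm has a single central hump, while the sheep worm has separate peaks, among them one in the bin from 4.50 to 5.00 with 7.14% of these abundant unigenes and one from -9.50 to -9.00 with 6.60%.

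Among 33 lists of *A. galli* genes fixed before the data were examined and with at least 5 measured members, 6 had a median below the central 95% of 10000 random lists of like abundance. Major sperm protein (159 unigenes) had a median log2 ratio of -1.77 (interquartile range -2.12 to -1.40; -1.38 under total scaling), with 52 unigenes at least 4-fold lower in condition B and 3 higher. Its most abundant unigene went from 1480750 normalized counts in condition A to 417202 in condition B, a log2 ratio of -1.83, and the next from 682084 to 240309 (-1.51). The tubulin list, matched by product name, had a median of -1.15 over 159 unigenes, with 18 lower and 3 higher. With 1 unigene per product name it was -0.61, inside the random range. Tubulins are the subunits of microtubules and the target of the benzimidazole drugs. By family, tubulin alpha chain had a median of -0.81 (21 unigenes) and beta chain -0.76 (20 unigenes), with 1 and 3 lower. Names with tubulin in them also include tau-tubulin kinases (73 unigenes, -1.54), so the list median does not stand for the drug target. The most abundant tubulin beta chain (-0.61) and alpha chain (-0.50) moved less than the tubulin list, and were at -0.23 and -0.11 under total scaling. Transthyretin-like proteins, a family of small secreted nematode proteins, had a median of -0.85 over 34 unigenes, which lay inside the random range with a pseudocount of 5, with a minimum mean of 50 and with ascaridid hits only. Transthyretin-like protein 5 was at -1.12, and transthyretin-like protein 46 at -0.29 (0.09 under total scaling).

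The list of potassium channels and the receptor latrophilin, a group that includes the targets of the drug emodepside, was also lower in condition B (94 unigenes, median -0.80). It holds potassium channels of many kinds, so its median does not stand for the drug's targets. With 1 unigene per product name the median was -0.85, inside the random range. Its most abundant members went opposite ways: T family of potassium channels protein 18, a muscle channel, at -0.86 and potassium channel subfamily T member 2, a sodium-activated channel, at 0.76. Eggshell and chitin genes had a median of -0.57 over 58 unigenes, with chondroitin proteoglycan 2, an eggshell component, at -0.78 and acidic mammalian chitinase, which degrades chitin, at -1.34; the list lay inside its random range with ascaridid hits only. Histones and replication genes had a median of -0.54 over 374 unigenes, inside the random range with 1 unigene per product name. In that list histone H2B, a core protein of the nucleosome, was at -0.94, and the RNA-directed DNA polymerase of transposon X-element, a mobile element enzyme, was at -1.09. The list thus takes in mobile-element polymerases by name, and the X-element family had a median of -1.43 over 29 unigenes. DNA polymerase (18 unigenes, -0.51) lay inside its random range. The list median does not stand for histone and replication genes alone. All 6 medians stayed negative under both other scalings. Total scaling gave smaller falls, with -0.77 for the tubulin list, -0.47 for transthyretin-like proteins, -0.42 for potassium channels and latrophilin and -0.18 for eggshell and chitin genes. All 51840 annotated unigenes with a mean of at least 10 normalized counts had a median of -0.25.

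**Figure D2:**
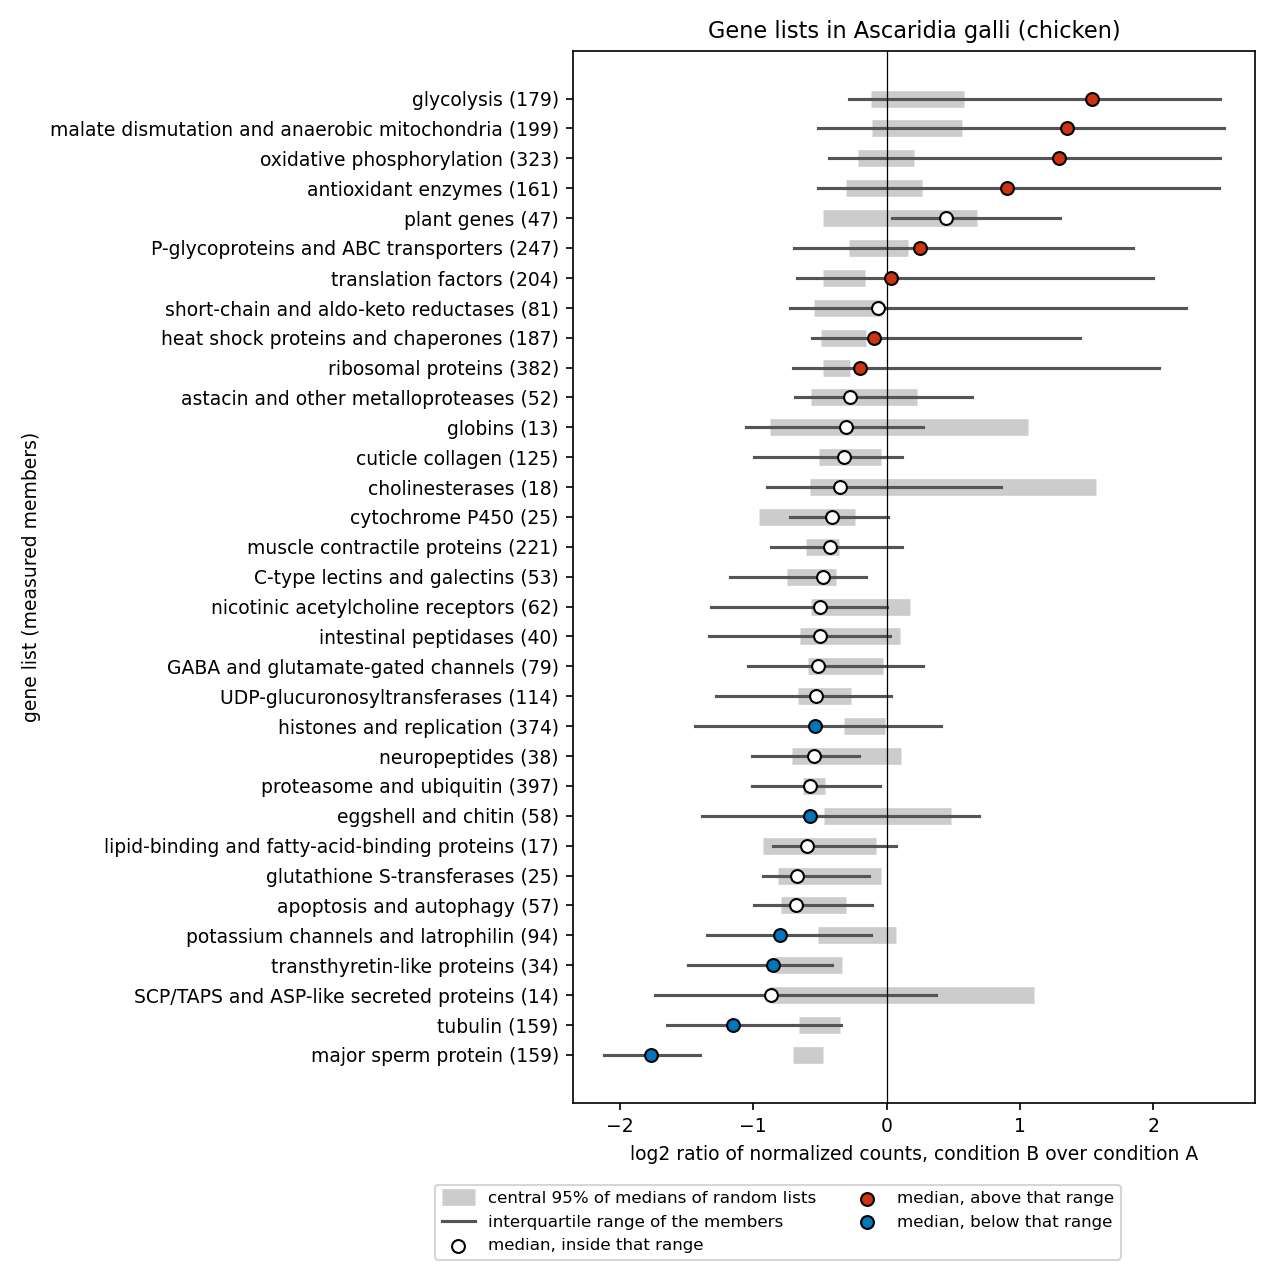
Median log2 ratio (condition B over condition A, x axis) of each gene list with at least 5 measured members in *A. galli* (y axis, members in brackets); lines are interquartile ranges and grey bars the central 95% of the medians of random lists of like abundance. Major sperm protein lies lowest at -1.77 and glycolysis highest at 1.54; the heat shock and ribosomal medians (-0.10 and -0.20) turn positive under total scaling (0.31 and 0.21).

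Lists of energy metabolism and protein synthesis were higher in condition B than random lists: glycolysis (179 unigenes, median 1.54), malate dismutation and anaerobic mitochondria (199 unigenes, 1.35), oxidative phosphorylation (323 unigenes, 1.29), antioxidant enzymes (161 unigenes, 0.90), P-glycoproteins and ABC transporters (247 unigenes, 0.25) and translation factors (204 unigenes, 0.03). With a minimum mean of 50 normalized counts the medians of all 6 turned negative (glycolysis -0.28, malate dismutation -0.50, oxidative phosphorylation -0.21), and only glycolysis and oxidative phosphorylation of the 6 stayed above their random lists. Glycolysis in turn lay inside with 1 unigene per product name, and oxidative phosphorylation with ascaridid hits only. Heat shock proteins and ribosomal proteins also lay above their random lists, but with medians of -0.10 and -0.20, which became 0.31 and 0.21 under total scaling. Ribosomal proteins lay inside with 1 unigene per product name and per best-hit protein, and heat shock proteins per best-hit protein (percentile 97.1). The heat shock list stayed above its random lists with a minimum mean of 50, with 1 unigene per product name and with ascaridid hits only. Its median was -0.33 in each of these settings. In these lists the unigenes with a best protein hit in an ascaridid worm, the kin of *A. galli*, moved apart from those with a best hit in another nematode. The split was not particular to these lists. Among all annotated unigenes, 27395 with ascaridid hits had a median of -0.58. The 9547 with hits in *Steinernema glaseri*, *Trichuris trichiura* or *Caenorhabditis remanei* had 2.01. Ascaridid glycolysis unigenes had a median of -0.37 (40 unigenes) and the others 1.89 (139 unigenes). For oxidative phosphorylation the medians were -0.53 (88 unigenes) and 1.91 (235 unigenes), and for malate dismutation -0.72 (41 unigenes) and 1.73 (158 unigenes). The ascaridid medians of glycolysis, of ABC transporters (-0.37) and of heat shock proteins (-0.33) turn positive under total scaling, while the medians with other hits are positive under every scaling.

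The most abundant members of these lists did not share their rise. Glyceraldehyde-3-phosphate dehydrogenase and enolase, both of glycolysis, were at -0.49 and -0.59 (-0.10 and -0.21 under total scaling). Malate dehydrogenase and phosphoenolpyruvate carboxykinase, which feed the anaerobic mitochondria of ascaridids, were at -0.33 and -0.13 (0.05 and 0.26 under total scaling). Cytochrome c oxidase subunit 1 and cytochrome b, both of the respiratory chain, were at 0.00 and 0.10 (0.38 and 0.48 under total scaling). Peroxiredoxin, a peroxide-reducing enzyme, was at -0.62 and thioredoxin domain-containing protein 12, of the endoplasmic reticulum, at -1.05. Because the abundant members weigh most in a sum, the summed counts of glycolysis (-0.42), malate dismutation (-0.49), oxidative phosphorylation (-0.04), antioxidant enzymes (-0.57), ABC transporters (-0.41) and translation factors (-0.37) had the opposite sign to the medians; those of oxidative phosphorylation and translation factors turn positive under total scaling.

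Among the remaining abundant members, heat shock protein 70, a chaperone, was at -0.75 and small heat shock protein ov25-1, a member of the alpha-crystallin family, at -0.10 (0.29 under total scaling). The ribosomal proteins 60S acidic ribosomal protein P0 and 60S ribosomal protein L8 were at -0.78 and -0.83. Elongation factor 1-alpha and elongation factor 2, which carry out steps of translation, were at -0.10 and -0.08 (0.28 and 0.30 under total scaling). ATP-binding cassette sub-family F member 2 and member 3, cytosolic ATPases without a membrane domain, were at -0.69 and -0.21 (the latter 0.17 under total scaling).

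**Figure D3:**
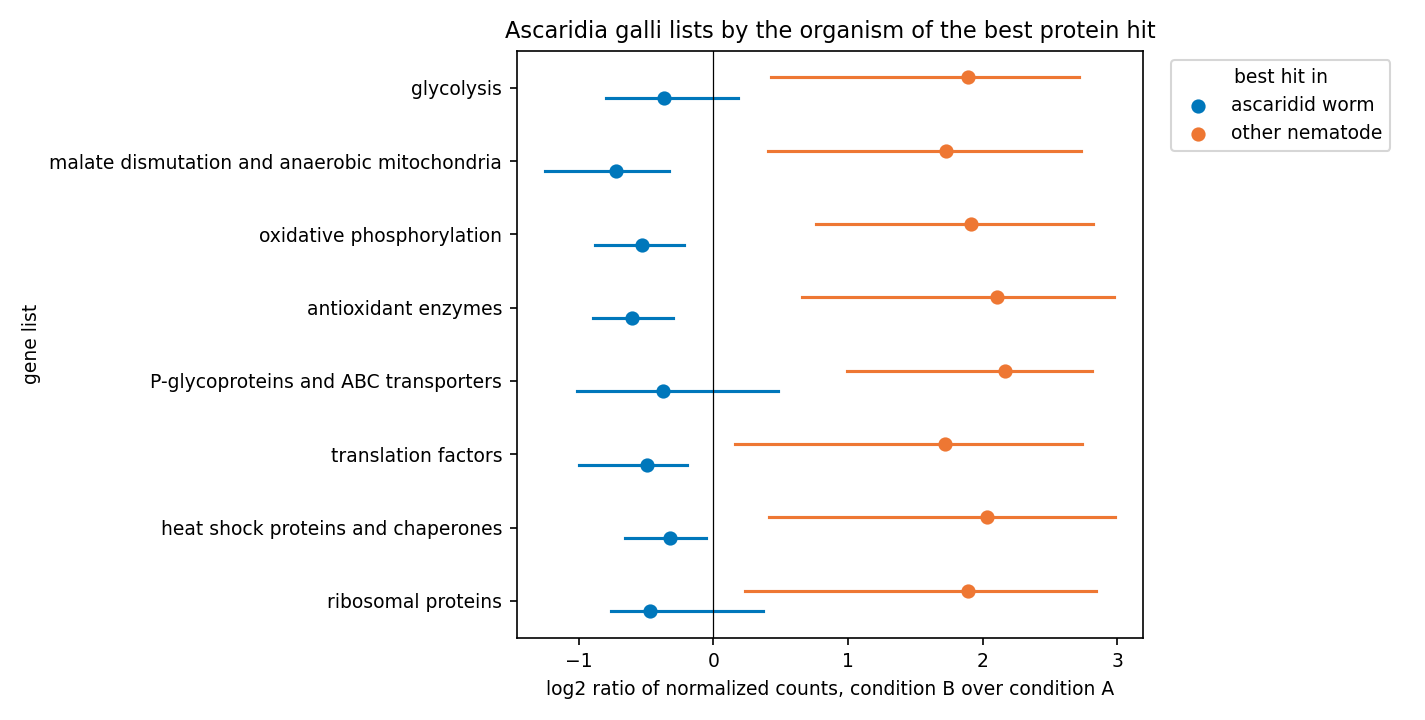
Median log2 ratio (condition B over condition A, x axis) of the *A. galli* lists above their random lists (y axis), split by whether the best protein hit lies in an ascaridid worm or in another nematode; lines are interquartile ranges. Members with other hits have medians from 1.72 to 2.17, and ascaridid members from -0.72 to -0.33, of which the ABC transporter, heat shock and glycolysis values turn positive under total scaling.

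The single *A. galli* transcripts with the largest rises toward condition B were of low or moderate abundance. DNA-directed RNA polymerase subunit alpha, a subunit of the bacterial-type enzyme, had a log2 ratio of 6.89 (counting interval 4.96 to 12.77), on 2.03 normalized counts in condition A and 357 in condition B. Ubiquinone/menaquinone biosynthesis methyltransferase ubiE, of quinone synthesis, was at 6.31, replicative DNA helicase, which unwinds DNA in replication, at 5.22, and Ribosomal L12 domain containing protein, of the large ribosomal subunit, at 6.02 (4.08 to 11.91). Eukaryotic products were among them too: H/ACA ribonucleoprotein complex non-core subunit NAF1, an assembly factor for small nucleolar RNA particles, at 6.25 (4.36 to 9.29), and Steroidogenic acute regulatory-like protein 1, a lipid carrier, at 4.87, from 33.5 to 1005 normalized counts. The Pol polyprotein of retrotransposable element R2, which inserts into ribosomal DNA, was at 5.44, from 42.6 to 1889. BRICHOS domain-containing protein C09F5.1 (6.14, interval 4.21 to 12.03), Xan ur permease domain containing protein (5.45), a nucleobase transporter, and Protein C09H10.9 (5.19) completed the 10.

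The transcripts with the largest falls were more abundant. Cystatin, an inhibitor of cysteine proteases that parasitic nematodes secrete, went from 12004 normalized counts in condition A to 208 in condition B, a log2 ratio of -5.84 (-6.13 to -5.57). The reductase FabG, a short-chain dehydrogenase of fatty acid synthesis, was at -4.79 (17497 to 632), and Carbonyl reductase NADPH 1, which reduces carbonyl compounds, at -4.38 (6531 to 314). Plasma kallikrein, a serine protease by name, was at -4.68, Ankyrin repeat domain-containing protein 12 at -4.48, Phosducin-like protein, a co-chaperone, at -4.93, and a zinc finger domain protein at -5.20. Cystathionine gamma-lyase, which makes cysteine, had 2 reads in condition B and a ratio of -5.89 with a wide interval (-11.79 to -3.95). A reverse transcriptase domain protein was at -4.15.

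Most other classes of worm genes lay inside the range of random lists in *A. galli*. These included cuticle collagen, the main protein of the body wall (125 unigenes, median -0.32), muscle contractile proteins (221, -0.42), intestinal peptidases (40, -0.50), astacin and other metalloproteases (52, -0.27), SCP/TAPS secreted proteins (14, -0.87), C-type lectins and galectins (53, -0.48) and globins (13, -0.30). The xenobiotic enzymes were inside as well: cytochrome P450 (25, -0.41), glutathione S-transferases (25, -0.67), UDP-glucuronosyltransferases (114, -0.53) and short-chain and aldo-keto reductases (81, -0.06). So were proteasome and ubiquitin genes (397, -0.57), apoptosis and autophagy genes (57, -0.68), neuropeptides (38, -0.54) and plant genes (47, 0.44). Across all lists of this worm 26 medians were negative, and 7 of them turned positive under total scaling. A list of photosynthesis products, added after the data were examined, lay above its random lists (79 unigenes, median 0.86, 26 at least 4-fold higher in condition B and 1 lower). Of the 50 matches of the plant list, 12 were ribulose-phosphate 3-epimerase, a sugar-phosphate enzyme that animals also have. Lipid-binding proteins had a median of -0.60 over 17 unigenes and a summed ratio of -1.20. Vitellogenin, the yolk protein, had only 4 measured unigenes (median 1.95), too few to compare, and the host, bacterial and cestode lists had 0 members.

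Receptors targeted by other anthelmintics lay inside their random ranges in *A. galli*. Nicotinic acetylcholine receptors, the target of levamisole, had a median of -0.50 over 62 unigenes, with the most abundant, alpha subunit 26, at -1.12. GABA and glutamate-gated channels, the targets of piperazine and the macrocyclic lactones, had a median of -0.51 over 79 unigenes, with the most abundant glutamate-gated chloride channel at -0.69. Cholinesterases by name (18 unigenes, -0.35) were led by Resistance to inhibitors of cholinesterase protein 3, a receptor chaperone, at -0.20 (0.19 under total scaling). The most abundant annotated transcripts overlapped in both conditions: lipid binding protein ag-50, a nematode polyprotein that carries fatty acids, fell by 1.24 on the log2 scale (1694430 to 715033 normalized counts), and a pair of C-type lectins, sugar-binding proteins, were at -0.03 (0.35 under total scaling) and -0.47.

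In the authors' deposited table for *A. galli*, 32874 unigenes are marked up, 15187 down and 102737 neutral. The lowest adjusted p in the authors' deposited table is 0.0551, and 6 unigenes have an adjusted p from 0.0551 to 0.0693 there, all higher in condition B, with log2 ratios from 7.41 to 9.19; 5 of them have no protein hit, and the other is an uncharacterized protein that went from 107 to 18287 normalized counts. In the authors' deposited table for *T. colubriformis*, 15301 unigenes are marked up, 17132 down and 11377 neutral, every adjusted p is 1 and the lowest unadjusted p is 0.1.

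In *T. colubriformis* nearly every abundant transcript differed between the conditions at the deposited scaling, and by large factors in both directions. Of 13843 unigenes with at least 1000 normalized counts in the higher condition, only 6.39% lay within 4-fold and 59.9% differed by more than 32-fold (14.5% and 72.5% under total scaling). At the deposited scaling 1 read was worth 2 normalized counts in condition A and 0.5 in condition B. Unigenes high in condition A therefore passed the minimum with fewer reads. Members of the same gene list stood on opposite sides, as with transthyretin-like proteins (7 higher and 21 lower), cuticle collagen (31 and 29) and heat shock proteins (35 and 35). Transthyretin-like proteins, GABA and glutamate-gated channels and glutathione S-transferases were the classes whose medians fell below random lists.

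Of 37391 *T. colubriformis* unigenes with at least 20 normalized counts in the higher condition, 14858 (39.7%) were at least 4-fold higher in condition B and 15572 (41.6%) at least 4-fold lower, 48.8% of these differences toward condition B. Scaling on total counts shifted the log2 ratios by 1.99 before the pseudocount of 1, which moved their median from 0 to 1.77, and gave 20365 higher and 10260 lower, 66.5% toward condition B; the trimmed mean of M-values shifted them by 1.02 and gave 17964 and 12125, 59.7%. Of the 17 gene lists with a negative median in this worm, 12 had a positive one under total scaling.

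Of 31 lists with at least 5 members in *T. colubriformis*, 3 lay below their random lists and none above, where 5 of 100 random lists were called in the simulation. Transthyretin-like proteins had a median of -2.66 over 34 unigenes (-0.71 under total scaling), with 21 at least 4-fold lower in condition B and 7 higher. The most abundant went from 85314 normalized counts in condition A to 369 in condition B (-7.85, and -5.86 under total scaling). The next went from 32694 to 4576 (-2.84, and -0.85 under total scaling). GABA and glutamate-gated channels, inhibitory channels of nerve and muscle, had a median of -4.89 over 8 unigenes (-4.35 under total scaling). A GABA receptor subunit was at -9.43 and GLC-4, a glutamate-gated chloride channel, at -6.41. Glutathione S-transferases, which conjugate xenobiotics, had a median of -4.43 over 9 unigenes (-2.88 under total scaling), with 5 lower and 4 higher; the most abundant was at -9.24, and Cytosolic glutathione S-transferase 1 was at 4.82. With 1 unigene per product name the transthyretin-like and glutathione S-transferase lists had too few members to compare (1 and 3), and the channels (5 members) lay inside their random range. The channels were also inside with a pseudocount of 5 and per best-hit protein, and the glutathione S-transferases with a minimum mean of 50.

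**Figure D4:**
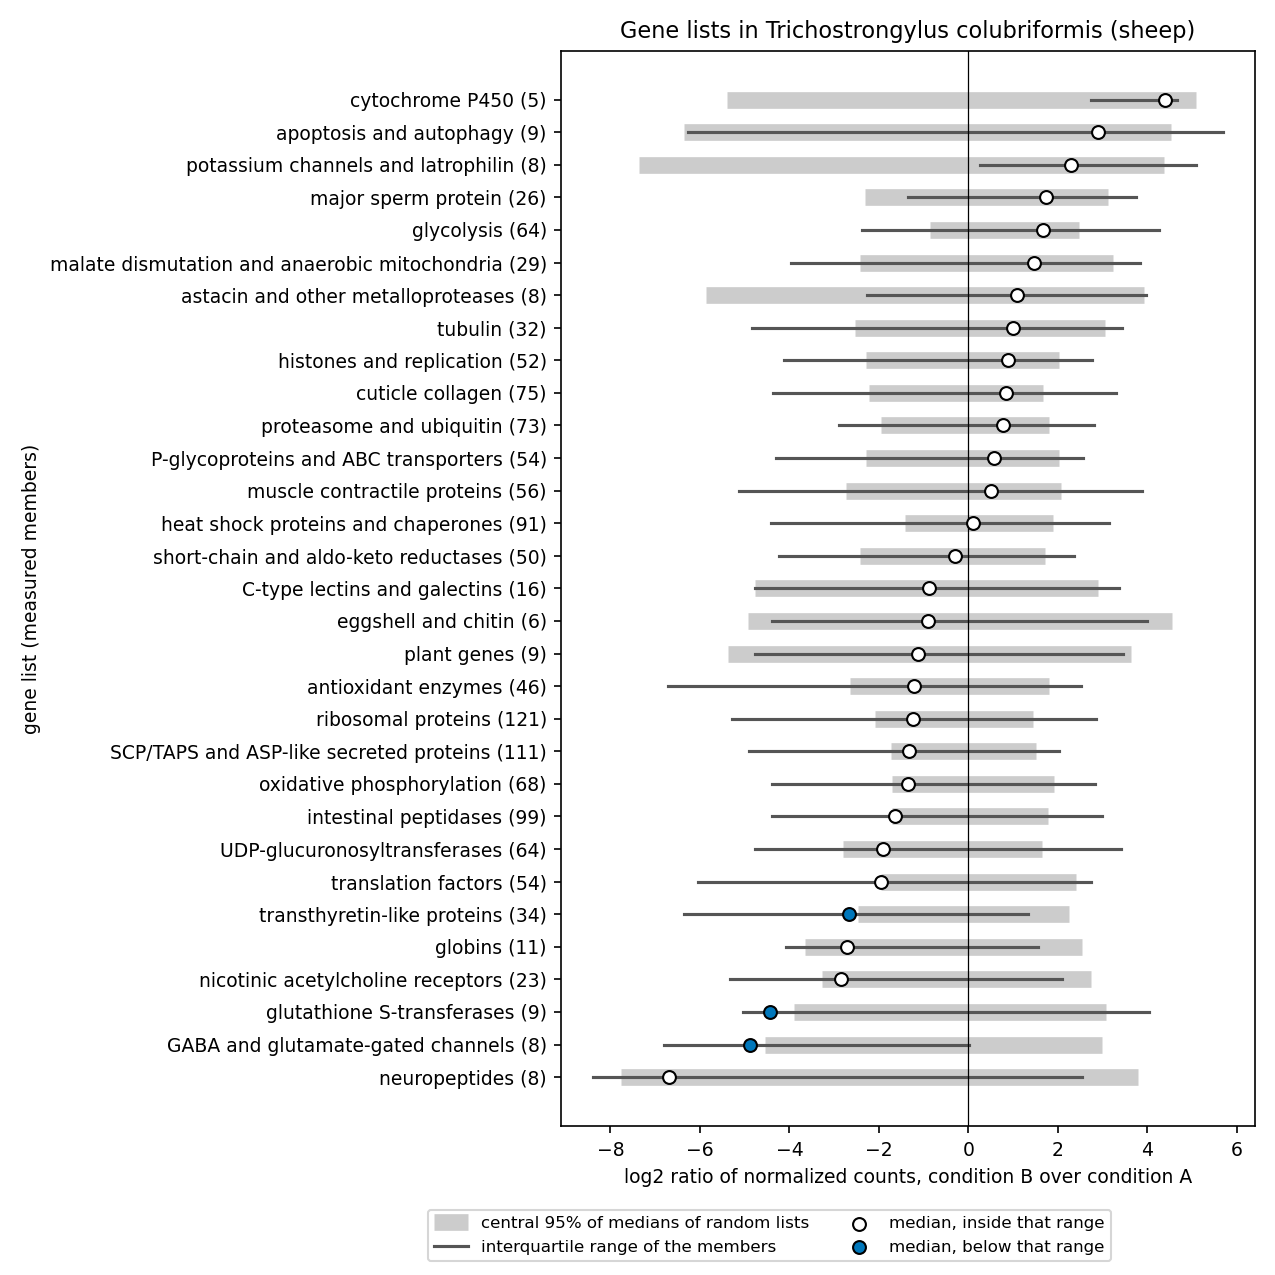
Median log2 ratio (condition B over condition A, x axis) of each gene list with at least 5 measured members in *T. colubriformis* (y axis, members in brackets); lines are interquartile ranges and grey bars the central 95% of the medians of random lists of like abundance. The 3 filled points lie below that range (-2.66, -4.43 and -4.89), and stay negative under total scaling (-0.71, -2.88 and -4.35), which turns 12 of the 17 negative medians positive.

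The transcripts with the largest rises toward condition B in *T. colubriformis* spanned signalling and regulatory products. An immunoglobulin I-set domain protein, of a class found in muscle and cell adhesion, went from 24.0 normalized counts in condition A to 75680 in condition B, a log2 ratio of 11.56 (10.50 to 13.07). A protein with the domain found in Dishevelled, Egl-10, and Pleckstrin, a membrane-targeting module of signalling proteins, was at 11.94 (10.26 to 15.16), an acyltransferase at 11.23, and ADT-1, a secreted metalloprotease of the ADAMTS family, at 10.72. A kinase domain protein was at 10.47 (9.83 to 11.24), and an ELMO/CED-12 family protein, which acts in engulfment of dead cells, at 10.51. A zinc knuckle protein (10.89), ubiquitinyl hydrolase 1, which removes ubiquitin (10.30), and a methyltransferase domain protein (10.24) were also among the largest rises.

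Falls were of the same order. A zinc finger protein of the C3HC4 type, a RING finger class common in ubiquitin ligases, went from 171112 normalized counts in condition A to 7.50 in condition B, a log2 ratio of -14.30 (-15.60 to -13.41). An ATP-dependent DNA helicase was at -13.00, a LINE-1 reverse transcriptase-like protein at -12.70, and a CAP-Gly domain protein, of a microtubule-binding class, at -12.28. 3-oxo-5-alpha-steroid 4-dehydrogenase, a steroid-reducing enzyme, had 1 read in condition B (-12.99, upper bound -11.69), and an LSM domain protein, of the RNA-binding Sm class, had 2 reads (-13.09, interval -19.39 to -11.61). An armadillo repeat protein (-12.29), a short chain dehydrogenase (-12.43), an integrase core domain protein (-12.33) and a GTPase-type domain protein of the TrmE class, of tRNA modification (-11.88), made up the remainder. The most abundant annotated transcripts showed both kinds of behaviour. A phosphatase led condition A with 3597150 normalized counts against 866011 in condition B (-2.05, and -0.06 under total scaling), while a bestrophin, a chloride channel, was at -10.33.

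Other drug targets of *T. colubriformis* differed among themselves. Nicotinic acetylcholine receptors had a median of -2.86 over 23 unigenes, inside their random range, with LEV-9, which helps to cluster levamisole receptors, at -8.54. The tubulin list, matched by product name as in *A. galli*, had a median of 1.0 over 32 unigenes, with 13 higher and 11 lower. Its median need not stand for the drug target. The most abundant tubulin alpha chain was at -1.97 (0.02 under total scaling). Potassium channels and latrophilin had a median of 2.28 over 8 unigenes, with 4 higher and 2 lower, while the most abundant member was at -2.40 (-0.41 under total scaling). Both lists were inside their random ranges, and their summed counts had the opposite sign to the medians (-0.59 and -0.58), which turns positive under total scaling. SCP/TAPS secreted proteins (111 unigenes, median -1.32) had 29 higher and 52 lower in condition B, and intestinal peptidases, which digest the host's proteins (99 unigenes, -1.65), had 31 and 44; the medians of both lists turned positive under total scaling, to 0.86 for the secreted proteins. Cuticle collagen (75 unigenes, 0.84) and heat shock proteins (91 unigenes, 0.09) were near even in their higher and lower members. Major sperm protein, lower in *A. galli*, had a median of 1.73 over 26 unigenes in *T. colubriformis*, inside its random range, with summed counts of the opposite sign (-1.76, and 0.23 under total scaling). Neuropeptides had a median of -6.70 over 8 unigenes and cytochrome P450 one of 4.38 over 5 unigenes, both inside ranges that were wide for so few members.

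Across the worms, 31 lists could be compared, and 1 lay outside its random range on the same side in both: transthyretin-like proteins, lower in condition B (medians -0.85 and -2.66). The *A. galli* call was lost with a pseudocount of 5, a minimum mean of 50 or ascaridid hits only, and the *T. colubriformis* list had too few members for a call with 1 unigene per product name. No list lay outside on opposite sides. Since several lists lay below their random lists in each worm, 1 shared list can arise by chance. The difference between the worms was not tested, and the shared side carries meaning only if A and B stand for the same treatments in both.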

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

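The alternatives with counts summed per best-hit protein, ascaridid hits only, a minimum of 1000 the trimmed mean of M-values for the lists, and other scalings for families and for lists split by best hit were chosen after seeing the data. The planned restriction to nematode hits was not run, since it removes nothing. No paired analysis was possible because each group has a single library and the conditions share no more than 1 replicate number.

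The counts of *A. galli* unigenes at least 4-fold higher and lower in condition B (25961 and 11163) became 4263 and 4973 with a minimum of 100, which reverses their order, 487 and 866 with a minimum of 1000, 8549 and 3177 among annotated unigenes, and 2894 and 1191 per best-hit protein; fewer features were tested in each of these. They became 40717 and 31194 at 2-fold and 5010 and 2670 when the counting interval had to clear 4-fold, by construction. Total scaling left 6767 lower. In *T. colubriformis* (14858 and 15572), total scaling left 10260 lower, annotated unigenes gave 7750 and 7881, best-hit proteins 5282 and 5699, and a minimum of 1000 gave 5026 and 7932. A pseudocount of 5 or no minimum changed none of these counts by more than 1.5 times. In *T. colubriformis* 1 read was worth 2 normalized counts in condition A and 0.5 in condition B. A minimum there asks for fewer reads of unigenes high in condition A, which favours the lower ones in the comparison of higher and lower. At the deposited scaling, the minimum of 100 shows that the excess toward condition B in *A. galli* came from unigenes with few counts. The higher minimums were not run under the other scalings.

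Of the 8 *A. galli* lists above their random lists, a minimum mean of 50 left 5 (4 of the same), 1 unigene per product name 4 (3 of the same), best-hit proteins 5 (4 of the same) and ascaridid hits 5 (3 of the same). Of the 6 below, 1 unigene per product name left 3 (2 of the same). Of the 3 in *T. colubriformis*, total scaling gave 6 with all 3 kept, a pseudocount of 5, a minimum mean of 50 or best-hit proteins left 2, and 1 unigene per product name gave 0: the channels lay inside (percentile 4.61), and the other lists had too few members.

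Medians of *A. galli* lists changed sign as follows; the cause was not tested beyond the loss of low-count members and of other hits. With a minimum mean of 50: ABC transporters -0.39, antioxidant enzymes -0.38, translation factors -0.44, glycolysis -0.28, malate dismutation -0.50, oxidative phosphorylation -0.21. With 1 unigene per product name: antioxidant enzymes -0.58, translation factors -0.55, glycolysis -0.22, malate dismutation -0.27, oxidative phosphorylation -0.33. Per best-hit protein: antioxidant enzymes -0.29, translation factors -0.53. With ascaridid hits: ABC transporters -0.37, antioxidant enzymes -0.61, translation factors -0.49, glycolysis -0.37, malate dismutation -0.72, oxidative phosphorylation -0.53. Under total scaling heat shock proteins were at 0.31 and ribosomal proteins at 0.21, and under the trimmed mean of M-values heat shock proteins at 0.057, because every ratio shifts upward.

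Of the *A. galli* lists below their random lists, major sperm protein stayed below under each alternative except 1 unigene per product name, which left 3 members, too few to compare. That alternative put tubulins (percentile 50.4), histones and replication (15.9) and potassium channels (6.35) inside the random range. Transthyretin-like proteins were inside with a pseudocount of 5 (3.38), a minimum mean of 50 (18.9) and ascaridid hits (3.10), and eggshell and chitin genes with ascaridid hits (22.8). Depth limits the transcripts named among the rises of *A. galli*, of which those with 2 reads in condition A have intervals wider than the ratio itself.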

Other observations

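The families described here and the tests of carry-over between libraries and of the scaling of major sperm protein were chosen after the results were seen; the lists of bacterial-only and sperm-associated products were written before their values were seen.

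Product families beyond the gene lists sharpen the picture of *A. galli*. Of 217 families with at least 15 unigenes, 40 lay below and 88 above random lists, where 5 of 100 random lists were called in the simulation. Random lists treat unigenes as independent, yet overlapping unigenes of the same best-hit protein had correlated ratios (0.62, against 0.09 in shuffles). The random ranges are therefore too narrow for families of related unigenes, and the same limit holds for the gene lists. Among those below were serine/threonine-protein phosphatase (147 unigenes, median log2 ratio -1.71, 50 at least 4-fold lower in condition B and 1 higher), tyrosine-protein kinase (107 unigenes, -1.48), tau-tubulin kinase 2 (38 unigenes, -1.60) and 1 (35 unigenes, -1.49), and Kelch-like protein 10, of ubiquitin ligases (18 unigenes, -1.57). Battenin, a lysosomal membrane protein (27 unigenes, -1.70), and receptor expression-enhancing proteins, which shape the endoplasmic reticulum (32 unigenes, -1.55), went with them. Some single sperm genes, chosen after their values were seen, were lower: BMA-SPE-4, a presenilin of sperm organelles, at -1.79, the unigenes of Sperm-specific class P protein 32 at -1.42 and -1.49, and those of Sperm transmembrane protein 9, which acts in fertilization, at -2.53 and -0.65. They do not stand for the class, since 44 products with sperm or testis in their names had a median of -0.58, that of all ascaridid unigenes. Reverse transcriptases and transposon products as a list were higher (742 unigenes, 1.21, 134 at least 4-fold higher and 31 lower). By family, LINE-1 reverse transcriptase-like proteins were higher (371 unigenes, 1.49), X-element and jockey polymerases lower (29 unigenes, -1.43, and 30 unigenes, -1.15). Also higher were acetolactate synthase (44 unigenes, 2.28) and 3-isopropylmalate dehydrogenase (41 unigenes, 2.11), both enzymes of branched-chain amino acid synthesis, while dihydroxy-acid dehydratase of the same pathway (20 unigenes, 1.40) lay inside its random range. The medians of the families named here keep their sign under total scaling and under the trimmed mean of M-values.

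In *T. colubriformis*, 5 of 72 families lay below random lists and 5 above, where 5 of 100 random lists were called in the simulation. The highest median among those above was that of carboxylic ester hydrolases (18 unigenes, 3.41, with 11 at least 4-fold higher and 7 lower). Their summed counts had the opposite sign at the deposited scaling (-1.24). Carboxypeptidases, digestive enzymes (16 unigenes, -6.98), serpins, inhibitors of serine proteases (15 unigenes, -3.64), Sre chemoreceptors of sensory neurons (17 unigenes, -3.60) and LINE-1 reverse transcriptases (36 unigenes, -3.84) had lower medians in condition B under each scaling; the summed counts of carboxypeptidases (-1.16) turn positive under total scaling. Kinase domain proteins (78 unigenes, 1.82), C2H2 zinc fingers, which bind DNA (70 unigenes, 2.21), hexosyltransferases (27 unigenes, 2.99) and WD domain proteins (43 unigenes, 2.77) had higher medians, with 23, 25, 6 and 10 members at least 4-fold lower. Their summed counts had the opposite sign (-0.59, -0.30, -1.88 and -2.17), and under total scaling only that of WD domain proteins stays negative.

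Many *T. colubriformis* unigenes fall into far-apart sets. Of those with at least 1000 normalized counts in the higher condition, 5989 had a log2 ratio of -5 or less and 4788 had 3 or more. The 5989 hold 59.9% of the reads of condition A and 1.02% of those of condition B, and the 4788 hold 0.43% and 57.0%. The sets were chosen on the ratio, with unequal cuts, so this contrast in reads follows from the choice. Unigenes in neither set hold the rest of the reads of both conditions. If the libraries came from worms of different species or diverged genotypes, a protein would often have overlapping unigenes going opposite ways, each by a log2 ratio of at least 3. This was so for 30.9% of 3258 proteins, against 25.3% to 27.7% in 200 shuffles among unigenes of like abundance, while in *A. galli* it was so for 0.20%, below its shuffles (0.82% to 1.14%). The ratios of overlapping unigenes had a correlation of -0.02 in *T. colubriformis* (0.001 in shuffles), so as a whole they were not opposed. In *A. galli* the correlation was 0.62. Carry-over of a fixed small share of reads predicts a narrow spread of the ratios in each set. The interquartile range in log2 was 2.16 over 1319 deeply read unigenes high in condition A and 2.01 over 1049 high in condition B. Their median reads in the lower condition were 0.85% and 0.68% of those in the higher. Transcripts truly present at low levels would widen the spread, and the limit was set after the data were seen. The spread therefore cannot decide on carry-over. The share of proteins with opposite unigenes leaves different worm material in the libraries as a hypothesis. Its excess over the shuffles was small, and overlapping unigenes showed almost no correlation. Carry-over stays open, and an effect of the extract stays open and untested.

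Unigenes of *A. galli* with bacterial-type names were higher in condition B, while the same list of bacterial-only products was lower there in *T. colubriformis* (20 unigenes, median -4.15, 5 higher and 12 lower). Products found in bacteria and not in animals (221 unigenes) had a median of 2.02, which is 2.59 above that of 40S and 60S ribosomal proteins (129 unigenes, -0.57), with separate interquartile ranges; 30S and 50S ribosomal proteins (93 unigenes) had 2.28. Low abundance alone is argued against, since the median lay 2.14 above the upper end (-0.12) for ascaridid unigenes of like abundance. More bacterial RNA in condition B, matched to nematode entries, is therefore a candidate explanation for this set, and for the unigenes with hits outside ascaridids in the energy lists, which were not tested apart; poly(A) selection removes much bacterial RNA, and what passed it is not known. Whether the extract changed the bacteria stays untested.

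Major sperm protein was lower in condition B of *A. galli*. Its median minus that of 40S and 60S ribosomal proteins was -1.20, a gap that no scaling changes, which argues against scaling, and unigenes of like abundance with short hits had a median of -0.64, which argues against a loss of short transcripts. Sperm-associated products other than major sperm protein (517 unigenes) had a median of -1.37, below random lists (-0.64 to -0.48), as less male germline material would give. That result rests on the tau-tubulin kinase (-1.54), phosphatase (-1.46) and tyrosine kinase (-1.39) families, whereas 44 products with sperm or testis in their names had -0.58, the median of all ascaridid unigenes. A lower share of males or of sperm in condition B may explain the pattern, and an effect of the extract on the germline stays open and untested.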
